A study of Drosophila melanogaster with 3 samples.

How the data were processed

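The samples were 3 biological replicates of whole Drosophila melanogaster embryos of both sexes, 0 to 24 hours old, from a transgenic line that expresses CG15011 with green fluorescent protein at its C-terminal end. Per the labels, chromatin was sheared by sonication to a size range of 200 to 800 bp, and the assay was transcription factor ChIP-seq with CG15011 named as the antibody target. A text label of each sample calls it an input control. The deposited notes list each peak list as derived from that replicate's own alignment and from a separate control alignment, so the 3 samples were taken as immunoprecipitated libraries. That control alignment is the same for every list and was not analysed here.

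Per the labels and the deposited notes, coordinates are on the dm6 assembly, each replicate's list was called on that replicate against the control, a pooled list was called on the 3 replicates together, and the optimal set was derived from these lists by a threshold on the irreproducible discovery rate (IDR), a measure of how well peak ranks repeat. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The lists are in narrowPeak format: the authors' signal value per peak is in column 7, and the deposited q column is −log10 of a q-value, used only to order peaks of equal signal. The q column has many ties at its top (1822 of the pooled peaks at 3.56), so peaks were ranked by signal. The last column is the summit's offset from the peak start. The scaling of signal between lists is not given in the sources used here, so signals were compared only within a list.

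Each replicate list and the pooled list hold exactly 30000 peaks, so their lengths say nothing about how many sites were bound. All 3237 optimal peaks were found with the same coordinates and signal in the pooled list, and they are its 3237 strongest peaks. The other 26763 pooled peaks are called the other pooled peaks. Most peaks of a list share 1 width (2531 of the optimal peaks are 444 bp wide). In the optimal set, 5 peaks repeat the coordinates of another with a different summit and were kept, and 2 have a summit offset outside the peak, for which the midpoint was used. Replicate 1 has 1 peak on chromosome Y. The read depth is unknown, so exact binomial intervals cover the counting of genes or peaks only.

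Gene positions came from Ensembl release 115 and sequence from the RefSeq copy of the same assembly, Release 6, whose arm lengths hold all peak coordinates. Transposable elements listed as genes were left out, which left 18164 genes on 2L, 2R, 3L, 3R, 4 and X, 13945 of them protein-coding. A summit within 500 bp of the TSS of any gene was called promoter, and other summits were assigned in the order 5′ UTR, coding sequence, 3′ UTR, other exon, intron, intergenic. The 20 gene lists hold 956 matched members (a gene in several lists counts in each), and 8 list symbols that matched no gene or more than 1 were left out. The 24 motifs were consensus sequences.

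There is 1 group, so no test between groups was made. Before the data were examined, the tests, lists, motifs and the rule for named genes were fixed. The rule names CG15011, the genes at the 25 strongest optimal peaks (TSS within 500 bp, or else the nearest gene), the 4 members with the strongest promoter peak in each list past an adjusted p of 0.05, and the 2 strongest members of every other list; 1 gene that the rule names is not reported here. Replicate support was the share of optimal summits inside a peak among the 3237 strongest of a replicate, with the mean over 20 random picks of as many peaks beside it. Locations were tested with a two-sided permutation test of 10000 redraws within arms outside assembly gaps, gene lists and biotypes (at least 20 genes) with two-sided Fisher's exact tests, arms with two-sided exact binomial tests against gap-free length, motifs and 8-mers (in at least 1% of windows) with two-sided exact McNemar tests of the window within 100 bp of the summit against the window centred 500 bp away on a random side, and the signal difference with a two-sided permutation test of 100000 resamples, with a 95% interval from 2000 bootstrap draws. P-values were adjusted by Benjamini-Hochberg within each family. These tests treat peaks and genes as independent, and neighbouring genes are not, so the p-values are too small for families of clustered genes. A gene counted as having a promoter peak if a summit lay within 500 bp of any of its annotated TSSs. Genes with more TSSs thus had more chances of a peak, and the tests did not adjust for this. Values per replicate are given as mean ± SD beside the main ones.

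Alternatives fixed in advance were the stronger 1618 optimal peaks, the optimal peaks supported by both other replicates with each replicate left out in turn, promoter windows of 250 and 1000 bp, the other pooled peaks as background for locations and sequences, only genes with a pooled promoter peak as background for lists, sequence windows within 50 bp, other numbers of peaks, and summit distances under 100 bp or a reciprocal overlap of 50% for replicate support. The optimal peaks kept without replicate 1, 2 or 3 numbered 2284, 2139 and 2333. These are still pooled peaks, so shifts in these sets also reflect the smaller number of peaks and do not isolate 1 replicate. Matching on GC content, counting transposable elements as genes, and pairwise rho with a replicate left out were added after seeing the data.

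The tests were tested on simulated data first. Uniform positions gave 0 calls over 20 runs of 7 classes, and moving 20% of positions to a TSS raised the promoter share to 31.0% from 13.6%, which was called. Peaks at random genes gave 3 calls over 100 runs of 20 lists, and a list of 31 genes at 5 times the odds was called in 78 of 100 runs. Exchanging summit and flank windows at random gave 0 calls among 3903 8-mers, and all of 50 8-mers planted in 3% of windows were called. Simulated genes received peaks independently of each other, and the exchange removed any difference in base composition between summit and flank windows. These rates therefore do not cover shared promoters, clustered gene families or base composition. Work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.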

Results

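Chromatin immunoprecipitation followed by sequencing was used to map where the protein product of CG15011 lies on the genome of Drosophila melanogaster embryos. The flies carried a transgene that joins green fluorescent protein to the C-terminal end of CG15011, an uncharacterised protein in the RefSeq annotation, and embryos of both sexes were taken from 0 to 24 hours of development. The 3 biological replicates form 1 group, so the comparisons set replicates against each other and the peaks against the genome. Each replicate has a list of 30000 peaks, a further 30000 were called on the pooled replicates, and the authors' optimal set holds 3237. The signal value of a peak is the authors', and it ranks peaks only within its own list. Read depth is unknown, since the lists hold no read counts, so no interval that needs depth is given.

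No peak summit lay within 500 bp of CG15011 itself (FBgn0035518, chromosome 3L, 4255991 to 4259152, minus strand of dm6) in any of the 5 lists. The strongest optimal peak within 20 kb of the gene (3L, 4239962 to 4240405) had a signal of 510.7 and ranked 461 of 3237, with its summit 15807 bp from the gene. The strongest peak within 20 kb ranked 766, 535 and 203 in replicates 1, 2 and 3.

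The 25 strongest optimal peaks had signals from 1667 to 3202 and each had an overlapping peak ranked 37 or better in every replicate. Of these, 16 lay within 500 bp of a transcription start site (TSS) and 8 in introns. The strongest (2L, 6612493 to 6612916, signal 3202) lay in an intron of CG11050, 1023 bp from a TSS. Other intronic peaks lay in Trl, which encodes the GAGA factor (3L, 14759302 to 14759738, signal 2582), and in Lk6, a protein kinase gene (3R, 11760876 to 11761223, signal 1969). A further intronic peak (2L, 480885 to 481282, signal 2728) lay in ush, with the zinc-finger gene cbt as the gene of the nearest TSS. Intronic peaks of CG32772, HmgZ, sbb and CG9663 had signals of 1900, 1835, 1764 and 1667. The remaining non-promoter peak (X, 12750846 to 12751623, signal 2985) lay in an exon of lncRNA:Vinr, nearest to the TSS of lncRNA:CR44619. The strongest promoter peak (X, 2703679 to 2704078, signal 2965) lay 36 bp from the TSS of Ugalt, a UDP-galactose transporter gene. Promoter peaks with signals above 2000 also lay at CG14100 (2569), at mRpL41 and lncRNA:CR44463 (2224), at Art3 and mRpS10 (2119), at lncRNA:CR31840 (2111) and at px (2082). The promoter peak of ph-p, a Polycomb group gene, had a signal of 1825, that of Chro, a chromodomain protein gene that shares its promoter with the TFIIH gene Ssl1, 1802, and that of Gapdh2, a glycolytic enzyme gene, 1746. The promoter peaks of CG31145, PNPase, Fkbp14, CG18549, Tina-1 and CG1888, and the peak shared by CenG1A and mRpS23, had signals from 1669 to 1963.

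The optimal set was drawn from the pooled reads of these replicates by a threshold on how well peak ranks repeat. It equals the 3237 strongest pooled peaks. Its presence in the replicates' lists is therefore in large part built in, and the shares below do not test whether binding repeats. Of the 3237 optimal summits, 80.7%, 87.6% and 79.3% lay in a peak among the 3237 strongest of replicates 1, 2 and 3, a mean of 82.5% ± 4.41 (SD, n = 3). Random picks of as many peaks from the same lists, which give the level of chance overlap and are not a fair contrast, gave 11.9%, 12.7% and 12.9%. In all 3 replicates at once, 1956 optimal peaks (60.4%) were found among the strongest 3237, against 0.201% for random picks, and 3111 (96.1%) were found at any rank. Over optimal peaks present in both lists of a pair, Spearman's rho of the signals was 0.749 for replicates 1 and 2, 0.651 for 1 and 3, and 0.684 for 2 and 3, across 3140 to 3170 peaks, which are not independent replicates. At promoter peaks the rho was higher, from 0.724 to 0.807, than at other peaks, where it was from 0.589 to 0.680. All lists were called against the same control alignment, which the replicates therefore do not test. The shares depend on how many peaks of a replicate are admitted: with 6474 in place of 3237 from each list, 86.9% of optimal peaks were found in all replicates, and with 1618, 33.4%.

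Promoters held 1384 of the optimal peaks, 42.8% against 13.6% of random positions on the same arms, a 3.14-fold excess (two-sided permutation test, 10000 redraws, p = 0.0002, the smallest they can give). Coding exons and 3′ UTRs were nearly empty of peaks. Only 4 summits (0.124%) lay in coding sequence against 13.7% of random positions, and 28 (0.865%) in 3′ UTRs against 4.42%, both with an adjusted permutation p of 0.00035. Intergenic sequence held 398 peaks (12.3%) against 27.2% (adjusted permutation p = 0.00035). Introns held 1368 peaks (42.3%), close to the 39.5% of random positions (adjusted permutation p = 0.00196), and the direction of this small difference turned under several alternatives. The 20 peaks in 5′ UTRs and the 35 in other exons did not differ from random positions (adjusted permutation p = 0.344 and 0.147), but these calls depend on the processing. Other exons were called as enriched without replicate 1 (1.72-fold, adjusted permutation p = 0.0106) and with a 250 bp window (1.59-fold, adjusted p = 0.00163) and as depleted with transposable elements as genes (0.221-fold, adjusted p = 0.000233), and 5′ UTRs as depleted with a 1000 bp window (0.345-fold, adjusted p = 0.00840). In the 3237 strongest peaks of each replicate taken alone, the promoter share was 45.0% ± 1.28, the intron share 40.2% ± 1.08 and the coding share 0.175% ± 0.0713 (SD, n = 3). Promoter peaks were stronger than other optimal peaks, with median signals of 284.0 and 230.4, a difference of 53.6 (95% bootstrap interval 42.3 to 65.6; two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). The size of this difference depends on which peaks are kept: it was 84.9 among the peaks supported without replicate 1, more than 1.5 times as large, 80 without replicate 2, 56.1 without replicate 3 and 68.3 among the 1618 strongest. The signal itself is the pooled one throughout, so an effect of a replicate was not separated from the selection of peaks. Down the pooled list, the promoter share went from 51.6% of the 1500 strongest peaks to 13.1% of the 1500 weakest.

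**Figure D1:**
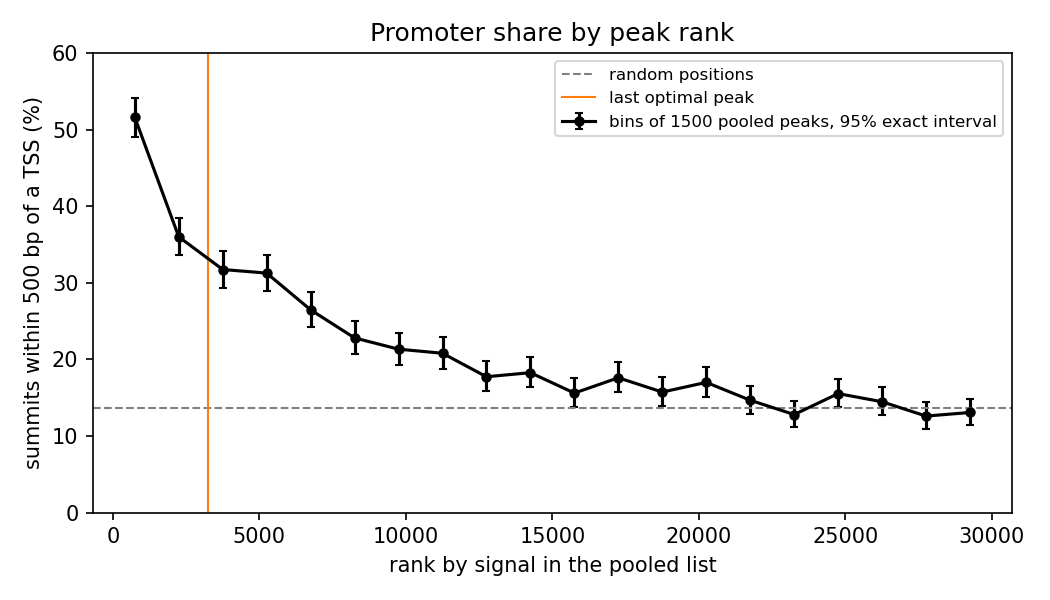
Share of pooled peak summits within 500 bp of a TSS (y axis, %) in 20 bins of 1500 peaks by signal rank (x axis), with exact 95% binomial intervals as bars. The share is 51.6% in the first bin and 13.1% in the last, next to the 13.6% of random positions (dashed line); the vertical line marks the last optimal peak, rank 3237.

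Around the TSS, the summits lay mostly on the upstream side, a measurement chosen after the peaks had been examined. Of the optimal summits within 500 bp of the nearest protein-coding TSS, 1066 were upstream and 211 downstream, an upstream share of 83.5% (exact 95% interval 81.3 to 85.5; two-sided exact binomial test against equal shares, p = 1.13e-137), with a median position of -154 bp. Among the 26763 pooled peaks outside the optimal set, the upstream share was 59.6% (58.1 to 61.1) and the median position -64 bp. The 200 bp upstream of the TSS held 597 optimal summits, 18.4% of the set, against 4.78% of the other pooled peaks. A summit between the TSSs of neighbouring genes that run away from each other is upstream of whichever is nearer, and cannot count as downstream. Of 1500 protein-coding genes with an optimal promoter peak, 832 had such a neighbour within 1000 bp. Equal shares are therefore not the level without a positional preference, and the p-value does not measure such a preference. How much of the upstream share remains without these summits was not tested.

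**Figure D2:**
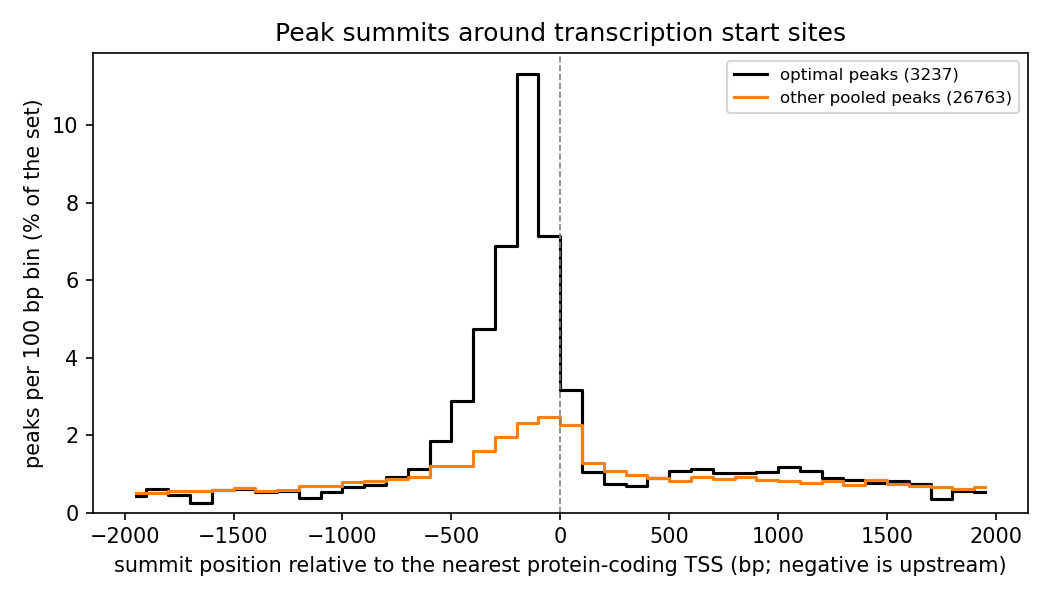
Position of peak summits relative to the nearest protein-coding TSS (x axis, bp, negative is upstream) as a share of each set per 100 bp bin (y axis, %). The 3237 optimal peaks (black) gather upstream of the TSS, with a median of -154 bp within 500 bp of it, and the 26763 other pooled peaks (orange) do so less.

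Genes of the cytosolic ribosome carried promoter peaks far more often than other genes. Of 91 cytosolic ribosomal protein genes, 60 (65.9%, exact 95% interval 55.3 to 75.5) had an optimal summit within 500 bp of a TSS, against 1440 of 13854 other protein-coding genes (10.4%), an odds ratio of 16.7 (95% interval 10.6 to 26.7; two-sided Fisher's exact test, p = 1.92e-36, adjusted over 20 lists p = 3.83e-35). The 3237 strongest peaks of each replicate alone gave 59.7 ± 4.16 of the 91 genes (SD, n = 3), from 55 to 63. Strong peaks of this list were at RpS27 (3R, 25247384 to 25247687, signal 1203), RpL7 (2L, 10200898 to 10201166, 902.5) and RpS10b (X, 19597892 to 19598141, 861.3). The summits at RpS27 and RpL7 were also within 500 bp of the TSS of another gene, and that at RpS10b was not.

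Heat shock and chaperone genes were the other list with more promoter peaks, 10 of 24 genes (41.7%, 22.1 to 63.4) and an odds ratio of 5.96 (2.36 to 14.5; Fisher's exact test, adjusted p = 0.000636). Its strongest peaks lay at the small heat shock gene Hsp27 (3L, 9383757 to 9384045, signal 888.8), at Hsp83, the fly Hsp90 gene (3L, 3192954 to 3193256, 853.8), at Hsc70-5, a mitochondrial chaperone gene (2R, 14255979 to 14256422, 570.6), and at Hsc70-4, a constitutive Hsp70 family gene (3R, 15242259 to 15242702, 261.4). The replicates alone gave 8.33 ± 1.15 of the 24 genes (SD, n = 3). The call was lost among optimal peaks supported by replicates 2 and 3, without replicate 1 (odds ratio 2.46, Fisher's exact test, adjusted p = 0.226), among those supported by replicates 1 and 2, without replicate 3 (2.76, adjusted p = 0.150), and among the 1618 strongest peaks (2.77, adjusted p = 0.258).

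Chemoreceptor genes and cuticle protein genes had almost no promoter peaks. The comparison with other genes did not adjust for the number of annotated TSSs per gene. None of 179 chemoreceptor genes had an optimal promoter peak, which allows a share of up to 2.04% (exact 95% bound), against 10.9% of other genes (Fisher's exact test, adjusted p = 2.51e-08), and none had one in any replicate's 3237 strongest peaks. Of 95 cuticle protein genes, 1 had a promoter peak, Cpr65Av (3L, 6140148 to 6140591, signal 166.3), against 10.8% of other genes (odds ratio 0.0877, 0.00219 to 0.501; Fisher's exact test, adjusted p = 0.00192). Among genes with any pooled peak at the promoter, the cuticle call was lost (odds ratio 0.139, Fisher's exact test, adjusted p = 0.116). With any 1 replicate left out, no cuticle gene had a peak.

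The other 16 lists did not pass the adjusted threshold, and their counts and strongest members follow. Among lists of general cell functions, 10 of 51 translation factor genes had a promoter peak (19.6%, Fisher's exact test, adjusted p = 0.183), with eIF4EHP at a signal of 1450 and eIF6 at 1178. The call for this list was gained with a 250 bp window (odds ratio 2.98, Fisher's exact test, adjusted p = 0.0179) and without replicate 2 (2.72, adjusted p = 0.0441). Of 73 mitochondrial ribosomal protein genes, 9 (12.3%) had one, mRpL41 and mRpS10 first. Of 70 oxidative phosphorylation genes, 5 (7.14%) had one, with ND-ASHI at 659.0 and ND-MWFE at 335.0, and of 32 proteasome genes, 2 (6.25%), Rpn5 at 278.6 and Rpn11 at 202.3. Of 47 replication and cell-cycle genes, 3 had one, with Dp, the partner of E2F, at 477.8 and RnrS, a ribonucleotide reductase gene, at 309.0. Of 31 spliceosome genes, 6 had one, with snRNP-U1-C at 274.2 and SF2 at 267.7. Apart from Rpn11 and Dp, the summit at each gene named for these lists was also within 500 bp of another gene's TSS.

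Among chromatin regulators, 6 of 29 Polycomb and Trithorax group genes had a promoter peak (20.7%, Fisher's exact test, adjusted p = 0.303), with ph-p at a signal of 1825 and brm, the Brahma remodelling ATPase gene, at 940.8. Of 14 insulator protein genes, 4 had one (28.6%, odds ratio 3.32, 0.760 to 11.5; Fisher's exact test, adjusted p = 0.183), with Chro at 1802 and Cp190 at 963.3. Among developmental lists, 8 of 32 muscle and mesoderm genes had one (25%, Fisher's exact test, adjusted p = 0.0701), with tin, the heart regulator tinman, at 518.7 and sls, a titin-like gene, at 294.9. None of the 8 Hox genes had one, which allows a share of up to 36.9%. Of 31 segmentation genes, 2 had one, nkd at 180.4 and hb at 160.3. Of 26 dorsoventral patterning genes, 3 had one, with cact, the inhibitor of Dorsal, at 510.9 and shn at 409.8. Of 31 neural development genes, 4 had one, with the pan-neuronal RNA-binding protein gene elav at 1092 and E(spl)m3-HLH at 751.2. Of 24 ecdysone response genes, 3 had one, with Ldh at 681.1 and the nuclear receptor gene Eip75B at 621.1. None of 19 antimicrobial peptide genes had one (up to 17.6%), and 2 of 49 odorant-binding protein genes did, Obp99b at 241.0 and Obp83g at 165.2. The summits at brm, Chro, Cp190, elav and E(spl)m3-HLH were also within 500 bp of another gene's TSS. Signals are the pooled ones, and some named peaks ranked low in a replicate. Examples are Hsc70-4 (11791 in replicate 3), ND-MWFE (8018 in replicate 3), hb (9340 in replicate 2) and Obp83g (8192 in replicate 1). The lists that were not called rest on few genes, and leaving out a replicate, which also leaves fewer peaks, moved several odds ratios by more than 1.5 times with no call: oxidative phosphorylation went from 0.637 to 0.177 without replicate 1 and 0.182 without replicate 2, segmentation from 0.572 to 0 without replicate 1 or 3 and 0.871 without replicate 2, and odorant-binding proteins from 0.352 to 0 without replicate 1 or 2 and 0.218 without replicate 3. The spliceosome list (1.32 in place of 2.00) and the Polycomb and Trithorax group (1.42 in place of 2.17) moved without replicate 1, and the dorsoventral (1.65 in place of 1.08), neural (1.87 in place of 1.23) and ecdysone (1.81 in place of 1.19) lists without replicate 2.

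**Figure D3:**
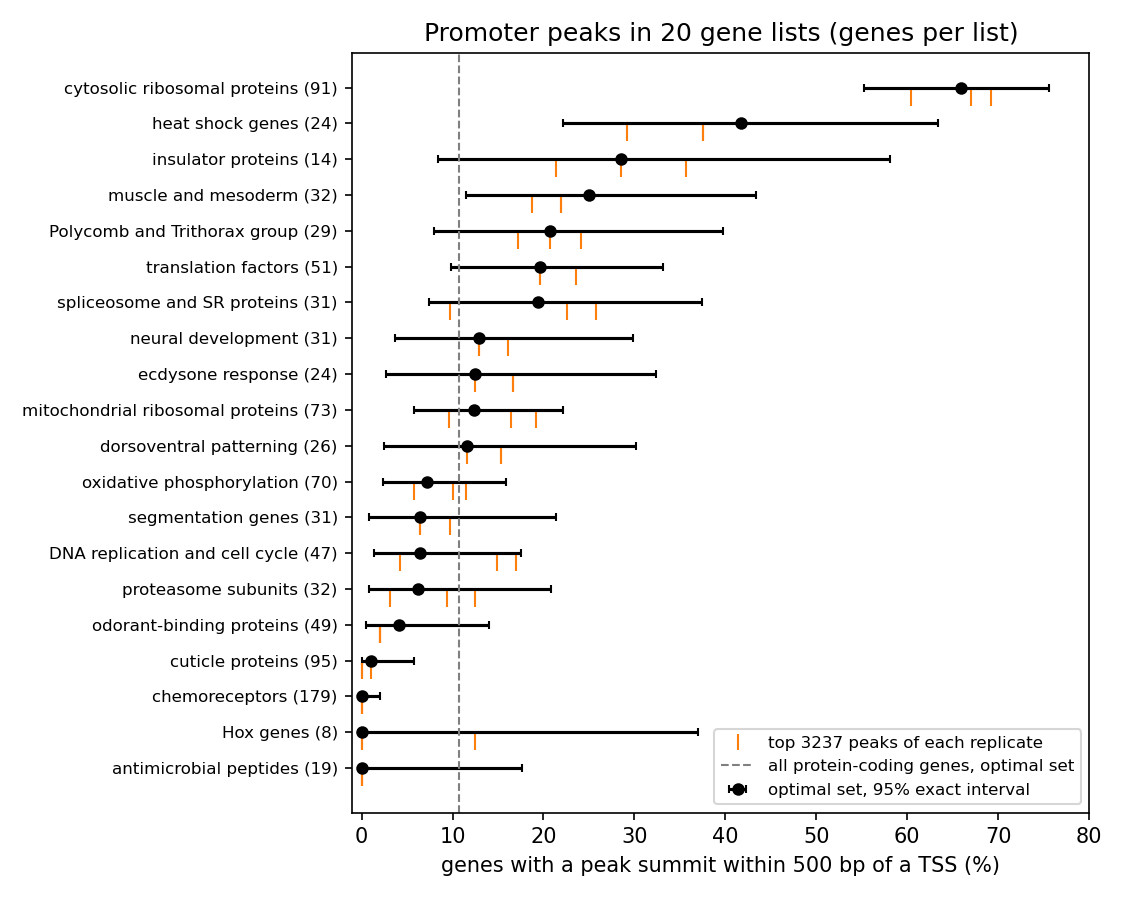
Share of genes with a peak summit within 500 bp of a TSS (x axis, %) for 20 gene lists (y axis, genes per list in parentheses); black points are the optimal set with exact 95% binomial intervals, orange ticks are the 3237 strongest peaks of each of the 3 replicates (equal values overlap), and the dashed line is the 10.8% of all protein-coding genes. The ribosomal protein list stands at 65.9% and the heat shock list at 41.7%.

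Protein-coding genes carried promoter peaks more often than genes of other kinds, counted per gene. A gene with more annotated TSSs had more chances of a peak, and the comparison of biotypes did not adjust for this. Of 13945 protein-coding genes, 1500 (10.8%) had an optimal promoter peak, against 4.29% of other genes (odds ratio 2.69, 2.29 to 3.17; Fisher's exact test, adjusted p = 1.08e-41). Shares were lower than among all other genes for non-coding RNA genes (157 of 3261, 4.81%, Fisher's exact test, adjusted p = 2.00e-24), tRNA genes (8 of 290, 2.76%, adjusted p = 3.75e-05), snoRNA genes (11 of 269, 4.09%, adjusted p = 0.00227), pseudogenes (2 of 268, 0.746%, adjusted p = 7.96e-09) and rRNA genes (0 of 99, up to 3.66%, adjusted p = 0.000208). The 32 snRNA genes, 3 of them with a peak, did not differ from other genes (Fisher's exact test, adjusted p = 1), with an odds ratio of 1.01 that went to 0.462 without replicate 1 and 0.401 without replicate 3. Without replicate 3, the odds ratio of pseudogenes was 0.0459 in place of 0.0726. Whether reads in repeated gene copies were kept is not given in the sources used here. The low shares of biotypes with repeated copies, such as tRNA and rRNA genes, therefore cannot be read as absence of binding. With a promoter window of 1000 bp, the snoRNA difference turned and was no longer called (odds ratio 1.28, Fisher's exact test, adjusted p = 0.179). Genes with divergent promoters, where another protein-coding gene starts within 1000 bp on the other strand and runs the other way, had a peak in 832 of 5052 cases (16.5%) against 668 of 8893 (7.51%) for the rest, an odds ratio of 2.43 (2.18 to 2.71; two-sided Fisher's exact test, p = 4.37e-58). A peak between such genes counts for both of them, so each can take a peak placed at its neighbour's TSS. The odds ratio is therefore raised by the counting itself, and its p-value treats paired genes as independent. How much of the difference remains without this was not tested.

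Peaks were spread over the chromosome arms close to their lengths, except on the small chromosome 4. Chromosome 4 held 10 peaks (0.309%, exact 95% interval 0.148 to 0.567) against 0.971% of the length (exact binomial test, adjusted p = 5.00e-05). Chromosome Y held none, but no pooled peak of any rank lay on Y either, so nothing is concluded from it. Arm 2L held 614 peaks (19.0%) against 17.2% (exact binomial test, adjusted p = 0.0160), and 2R, 3L, 3R and X held from 0.981 to 1.04 times the share of their length. Among the 1618 strongest peaks, arm 2L (adjusted exact binomial p = 0.231) and chromosome 4 (0.445 times its length share, adjusted p = 0.0767) were no longer called. Without replicate 2 the call of 2L was lost as well (1.09 times its length share, adjusted exact binomial p = 0.109), and without replicate 1 a call of X was gained (1.10 times, adjusted p = 0.0494).

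Sequences at the summits were poor in G and C and rich in 8-mers that hold CACTG. Windows of 201 bp around the summits were 35.1% G or C, and windows centred 500 bp away 43.0%. Of 3903 8-mers tested, 1283 were more frequent at the summits and 202 less frequent (exact McNemar test, adjusted over 8-mers), and 888 of the 1283 held at most 1 G or C. ATTTAAAA had the lowest p, with 364 summit windows against 139 flanking ones (exact McNemar test, adjusted p = 5.16e-22). Of the 30 enriched 8-mers with at least 4 G or C, 20 held CACTG or its reverse complement, and either is counted as CACTG below. CACTGAGA occurred in 103 summit windows and 12 flanking ones (8.58-fold, exact McNemar test, adjusted p = 3.26e-17), CACAGTGG in 135 and 35 (3.86-fold, adjusted p = 8.53e-14) and CACTGTGC in 129 and 38 (3.39-fold, adjusted p = 1.23e-11). Among the less frequent 8-mers, GCAGCAGC was in 19 summit windows and 114 flanking ones (exact McNemar test, adjusted p = 8.40e-16). Against other pooled peaks matched on promoter status and GC content, a comparison chosen after seeing the data, 26 8-mers were more frequent at the summits and 6 less (Fisher's exact test), and 16 of the 26 held CACTG.

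Of 24 known motifs, 7 were more frequent at the summits than in the flanks and 3 less frequent. The TATA box was in 37.8% of summit windows against 21.4% (1.76-fold, exact McNemar test, adjusted p = 3.15e-45), the Ibf insulator site in 7.72% against 3.77% (2.05-fold, adjusted p = 5.14e-11) and the DRE, the site of the promoter factor Dref, in 1.82% against 0.432% (4.21-fold, adjusted p = 8.11e-07). Motif 6 (2.31-fold, adjusted exact McNemar p = 7.84e-05), motif 7 (1.56-fold, adjusted p = 7.84e-05), motif 1 (2.75-fold, adjusted p = 0.0387) and the initiator (1.08-fold, adjusted p = 0.0373) were the others. CA repeats (0.482-fold, adjusted exact McNemar p = 3.64e-05), the GAGA repeat bound by the Trl protein (0.720-fold, adjusted p = 0.0105) and the longer GA repeat of the protein CLAMP (0.558-fold, adjusted p = 0.0373) were less frequent. The X-box of mammalian NFX1, in 4 summit windows and 3 flanking ones, the heat shock element (5 and 9), the Zelda site (3.92% and 4.63%) and the TCT initiator of ribosomal protein promoters (135 and 158) did not pass the test, nor did the other 10. These folds rest on few windows for the heat shock element, which went from 0.556 to 1 without replicate 1, and for the X-box, which went from 1.33 to 0.667 without replicate 1 or 3 and 0.333 without replicate 2. Calls were gained for CTCF without replicate 3 (2.6-fold in place of 1.68, adjusted exact McNemar p = 0.0302) and, as less frequent, for the Zelda site and the CRE with 50 bp windows (0.674-fold and 0.214-fold, adjusted exact McNemar p = 0.0490 and 0.0436). Motif 1 kept its call in 1 of 7 alternatives, the longer GA repeat in 2, and motif 7 and the initiator in 4 each. Against peaks matched on promoter status and GC content, none of the 10 main calls held in its direction: the TATA box stood at 37.7% of matched windows (1.00-fold, adjusted Fisher's exact p = 1), and the GAGA repeat was more frequent at the summits (4.14% against 2.5%, adjusted Fisher's exact p = 0.00699), while poly A, not called in the main test, was less frequent (0.726-fold, adjusted Fisher's exact p = 0.0142).

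CACTG sites, counted after the 8-mers had been seen, were densest to either side of the summits. In bins of 25 bp, they numbered 148 and 150 on the 2 sides next to the summit, rose to 285 from 100 to 75 bp on the left and 317 from 75 to 100 bp on the right, and lay between 144 and 178 beyond 250 bp. The mean of 59 other words made of the same 5 bases was lowest at the summit, 71.8 on its left, and 111 at 500 bp. The ratio of CACTG sites to that mean was 2.06 next to the summit on the left, 3.36 from 50 to 75 bp on the right, and 1.35 in the leftmost bin.

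**Figure D4:**
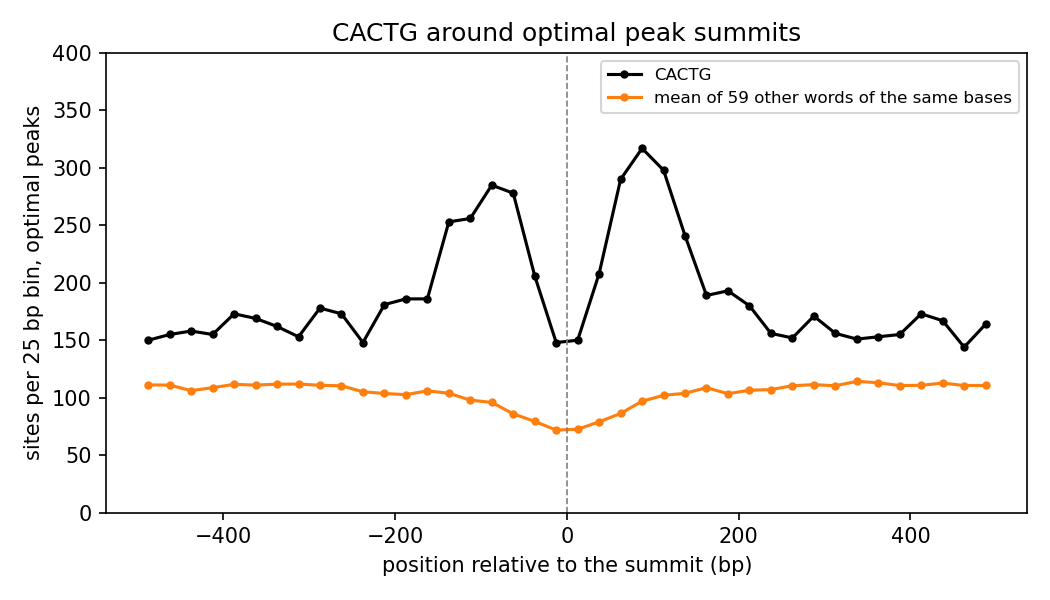
Number of CACTG sites on either strand (black) in bins of 25 bp (y axis) by position relative to the summit (x axis, bp) over the 3237 optimal peaks, with the mean of 59 other words of the same bases (orange). CACTG reaches 285 sites on the left and 317 on the right of the summit, and falls to 148 and 150 beside it.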

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

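The tests here were chosen after the main result was seen, except the test of genes without a neighbour, whose outcome was not known when it was set. The peaks of the pooled list outside the optimal set enter the gene comparisons of the report only through 1 alternative background, genes with any pooled promoter peak. Of the 31 ribosomal protein genes without an optimal promoter peak, 11 had such a peak at the promoter (35.5%). This was picked out as a signal in data outside the main measurement, above the 3 that a count of 0 allows. Of the 12414 other protein-coding genes without an optimal peak, 3132 had one (25.2%), and the difference was not past the threshold (odds ratio 1.63, 0.705 to 3.57; Fisher's exact test, p = 0.213).

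The ribosomal protein genes as a class had promoter peaks in 65.9% of cases. A peak at every promoter of a ubiquitously used gene class is argued against by the mitochondrial ribosomal protein, proteasome, translation factor and oxidative phosphorylation lists, which together had promoter peaks at 26 of 226 genes (11.5%, exact 95% interval 7.65 to 16.4). A neighbour that brings the peak is argued against as the whole cause by genes with no other TSS within 1000 bp, where 8 of 19 ribosomal protein genes had a peak against 6.76% of other genes (odds ratio 10.02, 3.48 to 27.5). Signal drawn to very strongly transcribed genes stays open: tRNA genes had fewer peaks than other genes (odds ratio 0.275, 0.117 to 0.550), but whether reads in their repeated copies were kept is not given in the sources used here, and expression was not analysed here. The single control shared by the lists stays open too, untested, and the design names no biological difference, so no biological explanation was tested.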

How the results depend on the processing

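Matching on GC content, transposable elements as genes, and pairwise rho without a replicate were chosen after the results were seen. Under each alternative run, the promoter share, the signal difference and the divergent promoters, where shared peaks count for both genes throughout, kept their direction and side of the threshold. So did the ribosomal protein and chemoreceptor lists, while the heat shock list kept its call in 4 of 7 alternatives and the cuticle list in 6 of 7. Over all single classes, arms, lists, biotypes and motifs, 186 comparisons were of a value called in the main analysis: 146 kept direction and side, 29 kept direction but lost the threshold, and 11 turned, 7 of which also lost it. Of 245 comparisons of an uncalled value, 10 gained the threshold in the same direction and 34 turned, 1 of which passed it. Named genes whose summit lies beyond 250 bp of the TSS have no value with that window. The promoter share ran from 28.4% (250 bp window, against 7.51% of random positions) to 54.5% (1000 bp, against 23.7%), and was 42.8% against 18.8% with the other pooled peaks as background. Support in all 3 replicates was 86.9% and 33.4% with 6474 and 1618 peaks admitted, 54.3% for summits within 100 bp and 48.0% for reciprocal overlap, and from 66.1% to 72.1% with a replicate left out, where fewer lists must hold the peak. Mean rho was 0.756 at promoter peaks and 0.636 at others, and from 0.651 to 0.749 without a replicate. Among the 1618 strongest peaks, 1 arm was called in place of 3 (both counts include Y, which holds no pooled peak), and 812 8-mers were higher in place of 1283, with fewer peaks tested. The higher 8-mers were 607 with 50 bp windows, 483 against other pooled peaks and 26 with GC matching. Of the 10 motif calls, 3 remained against other pooled peaks and none with GC matching, where the 2 calls were GAGA, turned, and poly A, which was not called before (0.726). There the fold turned for the initiator (0.977 and 0.955), GAGA (1.13 and 1.65) and the longer GA repeat (1.16 and 1.61). The intron fold turned to 0.926 (strongest 1618), 0.932 (1000 bp window) and 0.881 (other pooled peaks), and was from 0.997 to 1.05 without a replicate. The snoRNA odds ratio turned to 1.28 with the 1000 bp window. The other values that turned were not called in the main analysis. The other-exon fold turned to 0.221 with transposable elements as genes, where it passed the threshold, and to 0.940 against other pooled peaks, and the 5′ UTR fold to 1.05 with the 250 bp window. Arms 3L and 3R ran from 0.995 to 1.03 and from 0.994 to 1.01 without a replicate. The snRNA odds ratio turned to 0 (strongest 1618), 0.985 (250 bp) and 0.777 (1000 bp), and was from 0.401 to 0.983 without a replicate. The odds ratio turned to 0.921 (strongest 1618) and 0.810 (250 bp) for muscle and mesoderm, and to 0.405 (250 bp) for neural development. For ecdysone response it turned to 0.962 (1000 bp), and was from 0.952 to 1.81 without a replicate. Among genes with any pooled promoter peak it was 0.523 for ecdysone response, 0.785 for dorsoventral patterning and 1.05 for the proteasome. Among motifs, the X-box turned to 0.5 (strongest 1618) and was from 0.333 to 0.667 without a replicate, and poly A turned to 1.06 with 50 bp windows. The TCT initiator turned to 1.11 (strongest 1618) and 1.17 (GC matching), Su(Hw) to 0.565 and 0.520 (other pooled peaks and GC matching) and BEAF-32 to 0.917 (other pooled peaks). With GC matching, Zelda turned to 1.08, Pho to 1.13, E2F to 1.02 and CRE to 1.2. Where neither fewer peaks nor GC matching is named, the cause was not tested. Read depth is unknown, so what it limits was not tested.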

Other observations

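The tests of position and strength in this part were chosen after the results were seen; the tests of CACTG and of GC matching were set before their own outcomes were known, apart from the comparisons with other words. The summits at ribosomal protein genes sat at the TSS itself. Their median position was -21 bp (quartiles -60.5 and -1.25) over 60 genes, against -175 bp (-273.2 and -97.8) over 1440 other protein-coding genes with a promoter peak, a difference of 154 bp (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). Their peaks were also stronger, with a median signal of 393.8 against 292.0 (permutation test, p = 0.00789). A peak shared by neighbouring genes counts for each of them, so a peak at a gene's own TSS also counts as further off for its neighbour. The p-values for position and signal treat genes as independent. How much of either difference remains without shared peaks was not tested. The 10 heat shock genes with a peak had a median position of -133 bp (permutation test against the 1440, p = 0.360) and a median signal of 184.8 (permutation test, p = 0.145).

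Intronic peaks gathered near transcription starts. Of the 1368 optimal peaks in introns, which by definition lie more than 500 bp from a TSS, 598 (43.7%) lay within 2000 bp of one, against 28.3% of the other pooled peaks in introns (odds ratio 1.96, 1.75 to 2.20; Fisher's exact test, p = 2.60e-30) and 21.4% of random intronic positions. On chromosome 4, 6 of 80 protein-coding genes had an optimal promoter peak (odds ratio 0.671, 0.238 to 1.54; Fisher's exact test, p = 0.468). The arm held 0.957% of the other pooled peaks, next to its 0.971% of the length.

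The AT-rich 8-mers may follow from the base composition of the summit windows. Of the 888 enriched 8-mers with at most 1 G or C, 373 were still more frequent at the summits against other pooled peaks matched on promoter status alone. When those comparison windows were matched on GC content as well, 0 were. Part of the fall thus came with the change of background from flanks to other peaks. What makes the summits poor in G and C was not tested.

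CACTG differed from the AT-rich 8-mers, and a candidate explanation is a DNA sequence in the flanks of part of these sites. Base composition alone is argued against, since CACTG was in 42.8% of summit windows and 29.7% of GC-matched ones (odds ratio 1.77, 1.59 to 1.96). CACTG came first among the 60 words of its 5 bases, but it was picked from 8-mers enriched in these same summit windows. That choice favours a first place, and the interval does not allow for it. A sequence bound at the summit itself is argued against as the whole cause: it was predicted to be densest there, and the density of CACTG within 25 bp was 0.495 times that from 76 to 100 bp away (0.430 to 0.569), lower than base composition gives by the 59 other words (median 0.737, 1 word lower; odds ratio of CACTG against them 0.665, 0.575 to 0.766), though CACTG was still 2.06 times as frequent as those words beside the summit on the left, so binding there at part of the sites stays open. A summit called to one side of a single site was predicted to leave CACTG on 1 side only. Sites in the 3 bins of 25 bp beyond 50 bp on the left and on the right occurred together more often than chance gives (254 peaks with both where 191 are expected, 499 on the left only, 567 on the right only and 1917 with neither, odds ratio 1.72, 1.43 to 2.06), while 59 other words had a median odds ratio of 0.997 and 1 of them a higher one. More peaks had sites on 1 side only than on both, and an odds ratio over all peaks also rises if CACTG gathers in part of them. A single site beside the summit therefore stays open for the peaks with CACTG on 1 side. Of the sites, 54.6% on the left and 48.8% on the right read CACTG and not its reverse complement (odds ratio 1.26, 1.04 to 1.53). Which protein would bind at CACTG was not tested, and the share of peaks with CACTG was much the same among the 323 strongest peaks (42.1%) and the 323 weakest (41.2%).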
